A study of Solanum lycopersicum with 130 samples.

How the data were processed

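RNA was measured in shoots of tomato cultivar Micro-Tom, wild type or 35S::AtCKX2. Per the labels' protocols, seedlings 17 d old received 70 µL of a basidiospore suspension in 0.3% agar-water at the shoot apex and axillary buds, or agar-water alone, and stayed in a humid chamber for 48 h. Per the labels' protocols, polyadenylated RNA was selected out of 1000 ng of total RNA for libraries made with a stranded kit. The submitters' processing notes name CASAVA 1.8, FastQC, Trimmomatic, HISAT2, and featureCounts from Subread. Their order, parameters, strand setting, genome build and annotation are not given in the sources used here. The authors deposited 1 table of raw read counts per gene, with 34880 rows and 130 columns. Each column name equals the description label of 1 sample, and 0 columns were left over. Every row names a gene. The values were whole numbers with differing totals per library, so they were taken as counts with no normalization. How reads that match several paralogs were counted is not given in the sources used here, so genes with near-identical copies may share or lose reads, and antisense pairs could share reads if strand was not used.

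Groups came from genotype, treatment and time in the labels, with 5 libraries in each of 26 groups. Library totals were 0.78 to 11.48 M counts. Data were simulated from the library sizes, group means and trended dispersion of all 24 h libraries (17863 genes, 200 changed between infected and mock wild type). In these the test recovered 98.0% of genes changed 3-fold and 8.00% of those changed 1.5-fold, and 2.75% of its calls were false. At 30 d (18411 genes, 200 changed) it recovered 96.0% and 10.0%, with 7.02% false. In these simulated data, changes of 1.5-fold between infected and mock wild type were thus mostly not detected with 5 libraries per group. All simulated groups shared the trended dispersion, so groups that differ in spread were not simulated. Nor was a response to infection in the other genotype. The recovered and false shares therefore do not show how the test performs in those cases. Intervals and floors use counts pooled over the 5 libraries of a group, so they cover counting error only and not the spread between libraries. Reads without molecular identifiers are also not independent molecules.

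Before the data were examined, the design was fixed as 1 fit per time over all libraries of that time, so that the 4 groups shared 1 estimate of the spread (2 groups at 20 d), with 1 coefficient per group and no replicate block. The tests ran in R 4.3.3 with edgeR 4.0.16: TMM scaling, filterByExpr on the groups (its minimum count of 10 and minimum total of 15), glmQLFit and glmQLFTest, and Benjamini-Hochberg adjustment over the genes tested in a comparison at 0.05. Between 18056 and 19370 genes were tested per time. The 25 comparisons were infected against mock in wild type at 7 times and in 35S::AtCKX2 at 6, the difference of these responses at 6 times, and 35S::AtCKX2 against wild type in mock plants at 6. The standard error of a log2 fold change is its absolute value divided by the square root of the F statistic. CPM is a gene's count scaled by its library's total count, without TMM factors. Overlaps are given beside the overlap of independent lists, the product of the list lengths over the genes tested in both. The gene groups early, late and by genotype were defined after the comparisons were seen, among 16740 tomato genes tested at all times. Across-gene correlations use the same genes. Distances between libraries use log2 CPM with a prior count of 2 and TMM scaling over all 130 libraries, for 15915 genes with a mean log2 CPM above 2.

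The rule for named genes, fixed before the data were examined, took genes past 0.05 with an absolute log2 fold change of at least 1, a mean of at least 5 CPM in the higher group, no overlap between the infected and mock libraries and a name in the reference. The reference gene table supplied (assembly SLM_r2.1) matched 0 of the table's identifiers, so no tomato gene could be named, no gene list fixed in advance could be tested, and cytokinin oxidase genes of tomato were not picked out. In place of the named genes, the 2 largest rises and 2 largest falls that met the rest of the rule in wild type at 24 h, the time with most calls, are given by identifier. AtCKX2 is named from its row, AT2G19500, the Arabidopsis locus of that gene and the transgene named in the labels.

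Replicate pairs of a group were compared by a chi-square over genes with at least 20 counts in the pair. The lowest of 260 pairs had a chi-square of 1.30 per gene and the median pair 12.6, so none agreed within sampling noise. The alternatives were DESeq2's size factors within edgeR, DESeq2 1.42.0, no filter on low counts, only the groups compared, all 130 libraries in 1 fit, the replicate number as a block, and each library left out in turn. Leaving out wild-type mock replicates 4 and 5 at 5 d, 10 d and 20 d, infected wild-type replicates 2 and 5 at 48 h, and infected 35S::AtCKX2 replicates 4 and 5 at 48 h was added after seeing the data. For each comparison, 24 other splits of the same libraries were drawn with a fixed seed, 25 with the real one. For the interaction these were repeated, after the results were seen, on counts moved by q2qnbinom to the same quantile of a mean without the additive effects of infection and genotype, and tested on simulated data. Figures were drawn with matplotlib 3.10.9.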

Results

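Tomato shoots of the dwarf cultivar Micro-Tom were profiled by RNA-seq after inoculation with the fungus Moniliophthora perniciosa, the agent of witches' broom disease of cacao, or after mock inoculation. Plants were wild type or carried 35S::AtCKX2, a transgene that drives the Arabidopsis gene AtCKX2, which encodes a cytokinin oxidase/dehydrogenase and so breaks down the hormone cytokinin, from a viral promoter. The series held 130 libraries in 26 groups of 5. Wild type was sampled at 12 h, 24 h, 48 h, 5 d, 10 d, 20 d and 30 d after inoculation, and 35S::AtCKX2 at the same times except 20 d, which was not analysed here for that line. The deposited table gave read counts for 34879 tomato genes and for AtCKX2. Transcripts of the fungus were not analysed here. Library totals ran from 0.78 to 11.48 M counts, with a median of 5.61 M. Infected libraries were shallower than mock libraries at 12 h, with 4.40 ± 2.05 against 9.48 ± 1.96 M counts (SD, n = 10 each), and at 24 h, with 2.44 ± 1.17 against 7.11 ± 2.90 M (SD, n = 10 each). Over both genotypes they were also lower at 48 h, with 3.58 ± 1.48 against 4.83 ± 1.74 M, at 5 d, with 4.97 ± 0.963 against 6.87 ± 1.74 M, and at 10 d, with 6.11 ± 1.24 against 6.77 ± 0.822 M (SD, n = 10 each). At 10 d the genotypes went opposite ways. In wild type, infected libraries had 7.157 ± 0.3473 M against 6.212 ± 0.2805 M in mock, without overlap. In 35S::AtCKX2 they had 5.068 ± 0.7992 M against 7.326 ± 0.8155 M (SD, n = 5 each). The totals were close at 20 d, at 6.17 ± 0.511 and 6.34 ± 0.694 M (SD, n = 5 each), and at 30 d, at 5.31 ± 0.939 and 5.16 ± 1.24 M (SD, n = 10 each). The labels do not say whether replicates came from separate plants or pools, so the tests measure the spread between these samples only. The files do not pair the tomato identifiers with gene names. Genes are therefore described in groups set by their behaviour, and 4 identifiers are given in full.

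AtCKX2 transcript was abundant in every 35S::AtCKX2 library and close to absent in wild type. Its level in the 60 transgenic libraries ranged from 255 to 7194 CPM (counts scaled to a common library total). In wild type, 61 of 70 libraries had 0 AtCKX2 reads, and all 70 together had 21, with at most 6 in a library. The transcript was highest early. Mock plants had 4942 ± 1040 CPM at 12 h, 3384 ± 638 at 24 h, 5245 ± 992 at 48 h and 4280 ± 1042 at 5 d (SD, n = 5 each). The level was 1718 ± 785 CPM at 10 d and 335 ± 62.2 at 30 d (SD, n = 5 each). The mean at 12 h was 14.8 times that at 30 d, with no overlap between the libraries (two-sided exact permutation test on log2 CPM, p = 0.00794, n = 5 each, the smallest p this design allows). Infection lowered AtCKX2 at 48 h, with a log2 fold change of -1.10 ± 0.37 (SE) and an adjusted p of 0.0396 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. The level was 1277 and 1582 CPM in infected replicates 4 and 5, which lay nearest to infected 35S::AtCKX2 of 10 d, and 3293 to 5630 CPM in the other 3. Without both, an alternative chosen after this was seen, the log2 fold change was -0.67 and did not pass (adjusted p of 0.078 in edgeR's test). The call was lost in 9 of 28 other settings, the one without both replicates among them. Over the 28 the adjusted p from edgeR or DESeq2 ran from 0.00266 to 0.106. The rest of the 9 were the fits with only the mock and infected 35S::AtCKX2 groups (0.106), without wild-type mock replicate 5 (0.0728), without mock 35S::AtCKX2 replicate 2 (0.0588), 3 (0.0621), 4 (0.0691) or 5 (0.0696), and without infected 35S::AtCKX2 replicate 4 (0.0549) or 5 (0.0551), all as adjusted p in edgeR's test. At the other times the change did not pass: the log2 fold change was -0.31 at 12 h, -0.23 at 24 h, -0.44 at 5 d, -0.46 at 10 d and 0.19 at 30 d.

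**Figure D1:**
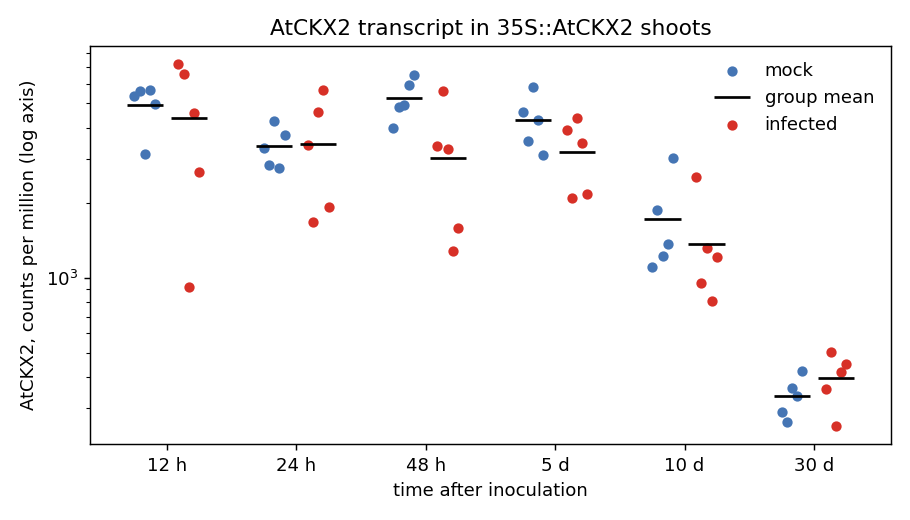
AtCKX2 level in CPM (log axis) in each 35S::AtCKX2 library against time after inoculation, in mock (blue) and infected (red) shoots, with black bars at the group means of 5 libraries. The mock mean was 4942 CPM at 12 h and 335 CPM at 30 d.

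Mock plants of both genotypes were compared to give the difference that the transgene line showed without the fungus. At each of the 6 times more genes passed than for infection in either genotype. At 12 h, 10394 of 19370 tested genes passed, 5046 higher and 5348 lower in 35S::AtCKX2. The counts were 12536 at 24 h (6137 higher, 6399 lower), 7920 at 48 h (4141 higher, 3779 lower), 11878 at 5 d (5799 higher, 6079 lower), 8773 at 10 d (4072 higher, 4701 lower) and 6041 at 30 d (3288 higher, 2753 lower). All were called by edgeR's quasi-likelihood test at a Benjamini-Hochberg adjusted p under 0.05. None of these 6 counts moved by more than 1.5 times under any other setting run. Depth and genotype coincided in mock plants at 24 h: wild-type libraries had 8.319 to 11.46 M counts against 2.406 to 6.087 M in 35S::AtCKX2. The part of depth in the genotype difference at 24 h was not separated. At the other shared times the totals of the mock groups overlapped. Without wild-type mock replicates 4 and 5, which lay apart from replicates 1 to 3 at 5 d and 10 d, 11909 genes passed at 5 d and 9310 at 10 d.

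The genotype difference recurred from 12 h to 5 d. Among 17871 genes tested at 12 h and 24 h, 3762 were higher at both against 1603.2 for independent lists of the same lengths, 4011 were lower at both against 1762.3, and 238 went opposite ways against 3362.0. Log2 fold changes correlated across 16740 genes with Pearson's r of 0.62 to 0.83 between any pair of the times from 12 h to 5 d. Between those times and 10 d, r was 0.21 to 0.51, and with 30 d it was -0.19 to -0.03. Genes are not independent replicates, and the groups compared at different times share no library. A group of 1703 genes was higher and a group of 2086 genes lower in 35S::AtCKX2 at each of 12 h, 24 h, 48 h and 5 d. At 24 h their median log2 fold changes were 1.65 and -2.19. At 10 d, 48.1% of the 1703 were again higher and 5.93% lower, and 41.6% of the 2086 were again lower and 5.37% higher. At 30 d the first group held 262 higher and 306 lower genes, and the second held 232 lower and 482 higher genes. Calls at all 6 times were made for 625 genes: 167 were always higher, 145 always lower and 313 changed direction between times.

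**Figure D2:**
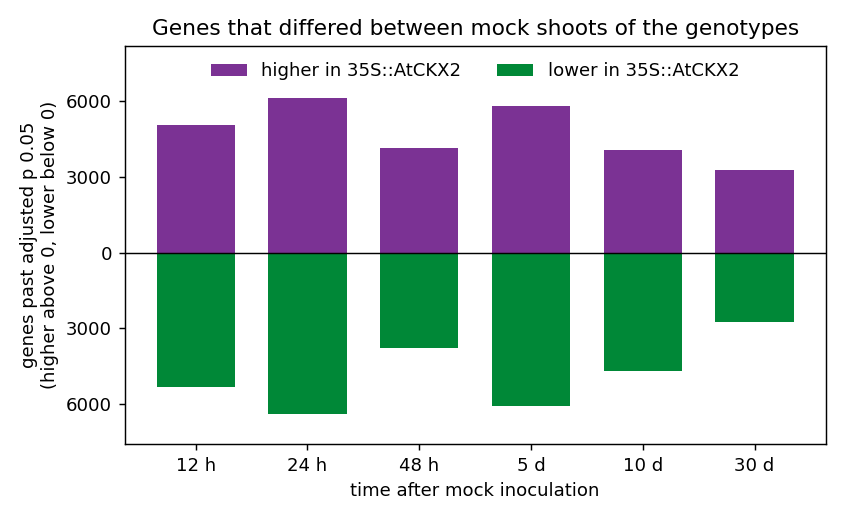
Number of genes higher (above 0) and lower (below 0) in 35S::AtCKX2 than in wild type in mock shoots, at each time after mock inoculation, at an adjusted p under 0.05 with 5 libraries per group. The total was 12536 genes at 24 h and 6041 at 30 d.

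Infected and mock wild-type plants were compared to give the response of tomato shoots to the fungus. Most genes were called in the first day. Depth and treatment coincided in wild type there: infected libraries had 3.987 to 7.197 M counts against 9.477 to 11.48 M in mock at 12 h. At 24 h they had 1.738 to 4.712 M against 8.319 to 11.46 M. At 12 h, 4779 of 19370 genes passed (1841 rose, 2938 fell), and at 24 h 6980 of 18056 (3296 rose, 3684 fell). Early changes recurred. Among 17871 genes tested at both times, 1058 rose at both against 304.5 for independent lists of the same lengths, 1996 fell at both against 579.4, and 44 went opposite ways against 857.1. Of the genes tested at every time, 920 rose at both 12 h and 24 h, by a median log2 fold change of 0.82 and 1.14, and 1963 fell at both, with medians of -0.82 and -0.90. At 48 h, 991 genes passed (344 rose, 647 fell). Of these early groups, 86 of the 920 rose again at 48 h and 1 fell, and 473 of the 1963 fell again and 1 rose. Infected replicate 5 of 48 h lay nearest to infected wild type of 24 h, and infected replicate 2 to mock wild type of 48 h. Without replicate 5, 52 of the 920 rose and none fell, and 186 of the 1963 fell and 2 rose. Without both, an alternative chosen after this was seen, 93 rose and 1 fell, and 275 fell and 3 rose, with 825 genes called in all. Without infected 35S::AtCKX2 replicates 4 and 5, also chosen afterwards, 152 of the 920 rose and 707 of the 1963 fell in wild type, and without infected 35S::AtCKX2 replicate 3 123 rose and 655 fell. Fitted with only the mock and infected wild-type groups, 8100 genes passed at 12 h (3952 rose, 4148 fell), and with DESeq2 and its own scaling 5974 did, of which 50.6% rose against 38.5% in edgeR. At 48 h, 1751 genes passed with DESeq2, 1897 with only those groups, 2013 with all 130 libraries in 1 fit and 1679 without infected 35S::AtCKX2 replicates 4 and 5, and the count fell to 599, 483, 497, 581 and 470 without mock replicate 1, 2, 3, 4 or 5 and to 647, 360 and 489 without infected replicate 3, 4 or 5, and was 1492 without infected 35S::AtCKX2 replicate 3.

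The 2 genes that rose most and the 2 that fell most in wild type at 24 h illustrate the range. Solyc08g062340.3 had 2 counts over the 5 mock libraries and 213 ± 62.8 CPM in infected shoots (SD, n = 5), a 4580-fold difference of the pooled counts (95% exact binomial interval 1270 to 37800, counting error only), with an adjusted p of 3.64e-12 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Solyc08g062450.1 went from 0.164 ± 0.113 to 297 ± 130 CPM (SD, n = 5 each). Its log2 fold change was 10.6 ± 0.66 (SE), with an adjusted p of 4.17e-10 in the same edgeR test. Solyc06g066420.3 went from 47.0 ± 34.9 to 0.373 ± 0.262 CPM (SD, n = 5 each). Its log2 fold change was -6.91 ± 0.92 (SE), with an adjusted p of 8.91e-06 in the same edgeR test. In wild-type mock shoots of the other times its mean was 0.131 to 6.73 CPM. It also fell at 12 h, by a log2 fold change of -3.7 in wild type and -2.86 in 35S::AtCKX2. In 35S::AtCKX2 at 48 h it rose (4.06, adjusted p of 0.0148 in the same edgeR test). Solyc06g008990.1 had 23.1 ± 9.33 CPM in mock shoots (SD, n = 5) and 0 counts in all 5 infected libraries, so it was at least 103-fold lower (against 3 counts over the group), with an adjusted p of 5.09e-07 in edgeR's test. Solyc06g008990.1 was at 0.618 CPM or less in every mock library of the times other than 24 h.

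**Figure D3:**
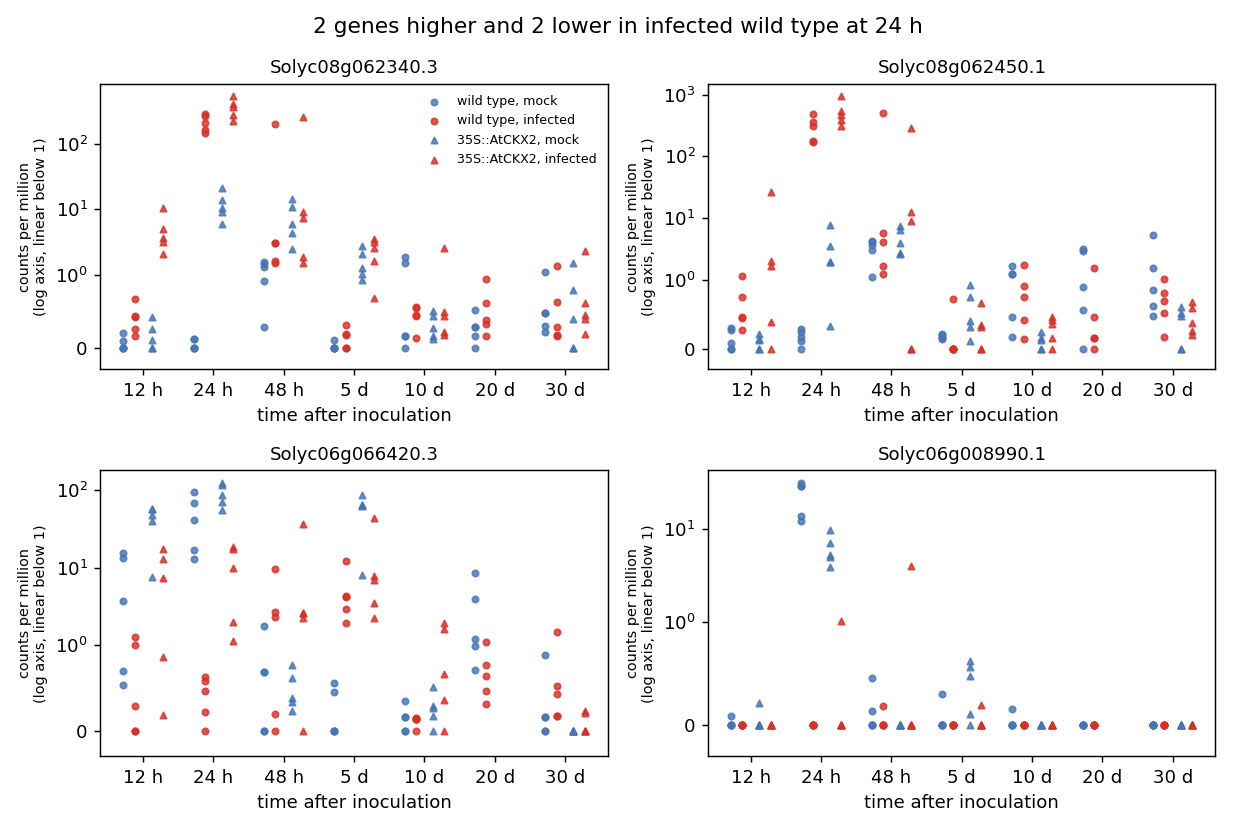
Level of 4 tomato genes in CPM (log axis, linear below 1) in each of the 130 libraries against time, in wild type (circles) and 35S::AtCKX2 (triangles), mock (blue) and infected (red). Solyc08g062340.3 averaged 213 CPM in infected wild type at 24 h against 0.0471 CPM in mock, and 1 infected library of each genotype stood at 199 and 259 CPM at 48 h.

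Few genes passed between infected and mock wild type at 5 d and 10 d, and more did later. At 5 d, 197 genes passed, of which 171 rose and 26 fell. At 10 d, 65 passed, 37 rising and 28 falling. Before adjustment, p in edgeR's test was under 0.05 for 2039 of 18711 genes at 5 d and 3587 of 18949 at 10 d. The low counts thus do not show that few genes changed. The counts of genes that passed then reached 2025 at 20 d (1237 rose, 788 fell) and 1969 at 30 d (946 rose, 1023 fell). Late changes overlapped with each other. Between 20 d and 30 d, 203 genes rose at both times against 60.4 for independent lists and 144 fell at both against 42.7, whereas 93 went opposite ways against 105.1. Between 12 h and 30 d the overlaps were 109 against 84.2 for rises and 104 against 152.4 for falls, with 190 opposite against 232.8. Between 24 h and 20 d they were 474 against 206.9 for rises and 236 against 149.9 for falls, with 193 opposite against 372.2. Of the 183 genes that rose at both 20 d and 30 d among those tested at every time, 15 had risen at 10 d and none fell there. Wild-type mock replicates 1, 2 and 3 lay nearest to infected wild type of the same time at 5 d and 10 d. The mean of their own group's other libraries included mock replicates 4 and 5. At 5 d and 10 d the root mean square difference in log2 CPM averaged 0.781 and 0.833 to replicates 4 and 5. It averaged 0.253 and 0.248 among replicates 1 to 3. Mock replicates 4 and 5 lay apart from them at 5 d, 10 d and 20 d, and without both of them 176 genes passed at 5 d, 52 at 10 d and 1409 at 20 d. The 10 d count rested on single libraries: it was 734, 197 and 592 without mock replicate 1, 2 or 3, 30 and 20 without mock replicate 4 or 5, and 40, 30, 14, 28 and 43 without infected replicate 1, 2, 3, 4 or 5. It was also 40, 38 and 39 without mock 35S::AtCKX2 replicate 1, 2 or 4, and 136, 38 and 36 without infected 35S::AtCKX2 replicate 1, 2 or 5. With DESeq2 it was 585, with 183 rising and 402 falling, so that the balance of directions turned, and another split of the same libraries called 891 genes. With all 130 libraries in 1 fit, 388 genes passed at 5 d, 341 at 10 d and 3181 at 20 d. DESeq2 called 396 genes at 5 d (73.0% rose, against 86.8% in edgeR) and 3168 at 20 d, and edgeR called 1268 at 20 d without infected replicate 1 and 1093 or 1074 at 30 d without infected replicate 1 or 5. Infected replicate 2 of 30 d lay nearest to mock wild type of 30 d.

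The same comparison was made in 35S::AtCKX2. The counts were 5859 at 12 h (2515 rose, 3344 fell), 9533 at 24 h (4921 rose, 4612 fell), 4516 at 48 h (2187 rose, 2329 fell), 1790 at 5 d (1066 rose, 724 fell), 2683 at 10 d (1345 rose, 1338 fell) and 1179 at 30 d (683 rose, 496 fell). Mock 35S::AtCKX2 12 h replicate 5 lay nearest to infected 35S::AtCKX2 of 12 h, and infected 12 h replicate 3 to that of 48 h. Depth and treatment coincided at 12 h in this line too, with totals of 1.153 to 5.368 M in infected and 5.919 to 11.41 M in mock libraries. At 24 h the totals overlapped, with 1.168 to 4.12 M against 2.406 to 6.087 M. With the spread shared by both genotypes, more genes were called than in wild type at each shared time except 30 d, but the order turned at 12 h, 24 h and 5 d when each genotype was fitted with only its own mock and infected groups: 2405 genes passed in 35S::AtCKX2 and 8100 in wild type at 12 h, 6952 and 9453 at 24 h, and 200 and 312 at 5 d. So fitted, 2209 and 1897 passed at 48 h, 4095 and 10 at 10 d, and 827 and 2279 at 30 d. These counts do not test the difference between the genotypes, which the interaction does. In the fit of all 4 groups, without wild-type mock replicates 4 and 5, 5534 passed at 10 d, and with all 130 libraries in 1 fit 1121 did. The early wild-type groups moved in 35S::AtCKX2 too. Of the 920 genes that rose early in wild type, 585 rose at 12 h and 704 at 24 h, and of the 1963 that fell early, 1559 fell at 12 h and 1599 at 24 h. Across genes the infection effects of the genotypes correlated with r = 0.74 at 12 h, 0.64 at 24 h, 0.40 at 48 h, 0.00 at 5 d, 0.30 at 10 d and 0.23 at 30 d. Solyc08g062450.1 rose in this line from 3.15 ± 2.89 to 531 ± 244 CPM at 24 h (SD, n = 5 each).

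The early wild-type groups were also read in 35S::AtCKX2 at 48 h and 5 d, in the fit of all 4 groups. At 48 h, 263 of the 920 genes rose and 36 fell, and 605 of the 1963 fell and 62 rose. Of the 920 genes, 231 rose and none fell at 5 d, against 34 and 4 in wild type. Of the 1963 genes, 411 fell and 1 rose, against 1 and 11 in wild type. The interaction passed for 90 of the 920 genes with a larger and 19 with a smaller log2 change in 35S::AtCKX2, and for 84 of the 1963 genes, all with a more negative change. The effects at 5 d correlated across genes with those of wild type at 24 h (r = 0.58) and not with those of wild type at 5 d (r = 0.00). With wild type at 12 h r was 0.54, and with the line's own effects it was 0.51 at 12 h and 0.54 at 24 h. The count of 1790 genes was 4594, 1164, 1060 and 796 without infected replicate 1, 2, 3 or 4, and 1045, 855 and 1034 without mock replicate 2, 3 or 4. Infected replicate 1 lay nearest to the mock group of its own line and time. The count was 2323 without wild-type mock replicates 4 and 5, 2888 with all 130 libraries in 1 fit, and 200 when only the mock and infected 35S::AtCKX2 groups were fitted.

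**Figure D4:**
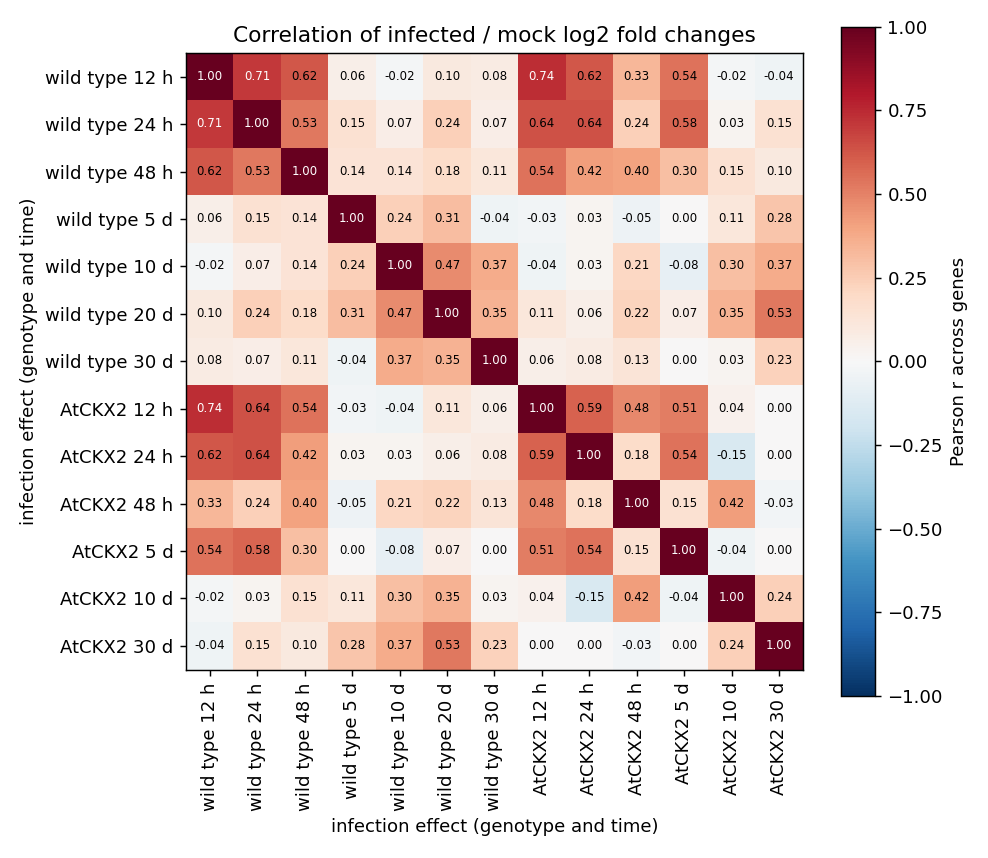
Pearson's r across 16740 genes between infected and mock log2 fold changes of each genotype and time, with both axes listing the 13 comparisons and colour and printed value giving r. Wild type at 24 h correlated with 35S::AtCKX2 at 5 d with r = 0.58, and wild type at 20 d with 35S::AtCKX2 at 30 d with r = 0.53.

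Late in infection, the 183 genes that rose at 20 d and 30 d in wild type included 42 that rose and none that fell in 35S::AtCKX2 at 30 d. Of the 126 that fell late in wild type, 38 fell and none rose there. Their medians at 30 d were 0.61 and -0.51 in 35S::AtCKX2, against 1.15 and -1.09 in wild type, where they had been selected. The 1179 genes at 30 d were 538 and 578 without mock replicate 1 or 2, 690 without infected replicate 2 and 1783 with DESeq2, and another split of the same libraries called 1458. That split was the real one with 1 library of each group exchanged.

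**Figure D5:**
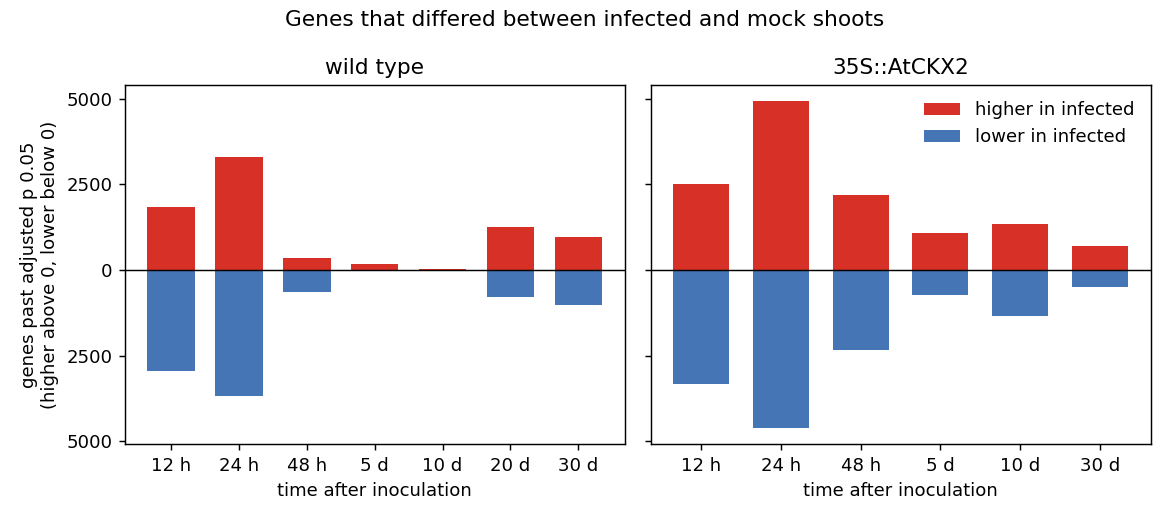
Number of genes higher (above 0) and lower (below 0) in infected than in mock shoots at each time, in wild type (left) and 35S::AtCKX2 (right), at an adjusted p under 0.05 with 5 libraries per group. The totals were 6980 and 9533 genes at 24 h and 65 and 2683 genes at 10 d.

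The interaction tested whether the response to infection differed between the genotypes. It passed for 28 genes at 12 h (14 with a higher and 14 with a lower log2 change in 35S::AtCKX2), 2842 at 24 h (1244 higher, 1598 lower), 850 at 48 h (234 higher, 616 lower), 605 at 5 d (346 higher, 259 lower), 921 at 10 d (565 higher, 356 lower) and 643 at 30 d (471 higher, 172 lower), in edgeR's quasi-likelihood test at a Benjamini-Hochberg adjusted p under 0.05. At 24 h, 1464 of these genes were called for infection in 35S::AtCKX2 but not in wild type, 437 in wild type but not in 35S::AtCKX2, 728 in both in the same direction and 182 in opposite directions. The absolute change was larger in 35S::AtCKX2 for 28.6% of them at 12 h, 78.0% at 24 h, 90.0% at 48 h, 71.9% at 5 d, 83.1% at 10 d and 54.0% at 30 d. Solyc08g062340.3 passed the interaction at 24 h (adjusted p of 5.33e-06 in edgeR's test). It rose 28.2-fold in 35S::AtCKX2 (95% exact binomial interval 24.9 to 32.0, counting error only), where mock shoots already had 12.2 ± 5.70 CPM and infected shoots had 360 ± 122 CPM (SD, n = 5 each). Solyc06g066420.3 did not pass the interaction at 24 h (adjusted p of 0.0966 in edgeR's test), and in 35S::AtCKX2 it fell from 91.3 ± 30.0 to 9.67 ± 8.15 CPM (SD, n = 5 each). The interaction counts moved with single libraries, and their lowest and highest values with 1 left out were 15 (wild-type mock replicate 5) and 69 (mock 35S::AtCKX2 replicate 5) at 12 h, 2089 (infected 35S::AtCKX2 replicate 5) and 4809 (mock 35S::AtCKX2 replicate 1) at 24 h, 457 (wild-type mock replicate 5) and 1680 (infected 35S::AtCKX2 replicate 2) at 48 h, 307 (infected wild-type replicate 3) and 2399 (infected 35S::AtCKX2 replicate 1) at 5 d, 497 (infected 35S::AtCKX2 replicate 5) and 1936 (infected 35S::AtCKX2 replicate 1) at 10 d, and 348 (infected wild-type replicate 5) and 1132 (infected 35S::AtCKX2 replicate 1) at 30 d. Infected 35S::AtCKX2 replicate 1 lay nearest to mock 35S::AtCKX2 of the same time at both 5 d and 10 d. Without wild-type mock replicates 4 and 5 they were 296 at 5 d and 1762 at 10 d, with DESeq2 202 at 12 h, 1509 at 48 h, 1212 at 5 d, 1626 at 10 d and 1165 at 30 d, and another split of the 12 h libraries called 555 genes. With all 130 libraries in 1 fit they were 57 at 12 h, 1494 at 48 h, 1322 at 5 d and 153 at 10 d.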

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

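The splits for the interaction with the additive effects taken out, and the tests of a batch, a swap, library size, wild-type material and 24 h libraries under a 5 d label were chosen after the result was seen. Those of TMM scaling, of single libraries at 5 d and of wild-type mock replicates at 5 d were set before their results were seen, and the other splits of libraries were planned.

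Differences between the genotypes in the response to infection were called for 28 genes at 12 h, 2842 at 24 h, 850 at 48 h, 605 at 5 d, 921 at 10 d and 643 at 30 d. Splits that exchange mock and infected libraries within each genotype also break up the response common to both, which adds to the spread, so the additive effects of infection and genotype were first taken out of the counts. The real split then called 2787 genes at 24 h against at most 510 in the 24 others, 839 against 220 at 48 h, 596 against 0 at 5 d, 913 against 0 at 10 d and 639 against 0 at 30 d. No other split drawn called as many for these (1 of 25 as large each, the smallest share that 25 splits can give). At 12 h, 3 of 25 splits called as many as the 27 of the real one. The highest other called 979, and the cause of this was not tested.

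Within groups, 54 tests for an outlying library were made (total counts in every group, AtCKX2 in 35S::AtCKX2 groups and the 4 identifiers in 24 h groups), and 5 found one, where chance alone gives about 2.7. The total count of infected wild type 20 d replicate 4 was 5.27 M against 6.26 to 6.48 M in the others. Mock wild type 30 d replicate 5 had 4.70 M against 6.31 to 6.85 M, and infected 35S::AtCKX2 24 h replicate 5 had 4.12 M against 1.17 to 1.95 M. AtCKX2 stood at 3150 CPM in mock 35S::AtCKX2 12 h replicate 3, with the others from 4960 to 5650 CPM. Solyc06g008990.1 stood at 1.03 CPM (2 reads) in infected 35S::AtCKX2 24 h replicate 1 and at 0 in the others. With the others at 0, any read in 1 library gives an outlier by this rule, so that test is not informative. In infected wild type at 24 h the gene was at 0 in all 5 libraries, where no outlier can be found. Both tests are counted among the 54.

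Wild-type mock replicates 4 and 5 lay apart from replicates 1 to 3 at 5 d, 10 d and 20 d. The root mean square difference in log2 CPM was 0.498 between 4 and 5 at 10 d, 0.248 on average among 1 to 3, and 0.833 across. A batch shared by all wild-type libraries of a replicate number is argued against at 10 d and 20 d, since the difference between these replicates correlated with that in infected wild type by 0.121 and -0.449, but it stays open at 5 d, where r was 0.3, and the difference recurred among the mock groups, with r = 0.543 between 5 d and 10 d, 0.282 between 5 d and 20 d and 0.326 between 10 d and 20 d. A swap with infected libraries is argued against as well, because 0 infected libraries at the 3 times lay nearer to mock replicates 4 and 5 than to the other infected ones, and so is library size as the cause at all 3 times, since the ratio of mean totals was 0.987 at 10 d, although it was 0.807 at 5 d and 0.909 at 20 d. A batch of mock libraries alone, plant state, hour of harvest and an exchange with samples outside these groups stay open, and no biological explanation was tested.

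AtCKX2 fell 14.8-fold in mean CPM from 12 h to 30 d in mock 35S::AtCKX2 plants, and 17.6-fold with TMM scaling over all libraries. Wild-type material would have to make up 94.3% of the 30 d samples to give the TMM-scaled fall, which leaves no room for genes 2-fold below wild type, yet 957 genes were called at least 2-fold lower at 30 d. Of 16 genes at least 8-fold lower at 12 h to 5 d and present in wild type at 30 d, the median stood at 115% of the wild-type level at 30 d, a value that a mixture does not forbid. Of these genes, 7 lay under 94.3%, with a lower quartile of 61.4% and the lowest at 0.39%. Rescaling by other transcripts is argued against, since the TMM-scaled ratio of 17.6 was no smaller. A biological change of the transgene's expression with shoot age may account for the fall, but age and time of sampling coincide here and this stayed untested.

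The infection response of 35S::AtCKX2 at 5 d correlated across genes with that of wild type at 24 h (r = 0.58 over 15915 genes) and not with that of wild type at 5 d (r = -0.0123). Over 16740 genes, r was also 0.54 with wild type at 12 h, and 0.51 and 0.54 with the line's own response at 12 h and 24 h. No single library decides this, since r stayed at 0.524 or more with any 1 of the 10 libraries left out, although infected replicates gave from 0.017 to 0.51 when taken singly. Libraries of 24 h labelled as 5 d are argued against, as 0 of the 5 infected libraries lay nearest to the infected 24 h group. Wild-type mock replicates 4 and 5 did not hide the same response in wild type, since r with wild type at 5 d was 0.0238 without them. At 48 h the response of 35S::AtCKX2 correlated with its own at 12 h by 0.48, but at 24 h and 5 d by only 0.18 and 0.15. Of the early wild-type groups, 263 of the 920 genes rose and 36 fell in this line at 48 h, and 605 of the 1963 fell and 62 rose. Whether an early response lasted through 48 h is thus not settled, and none is claimed. The explanation stays open, with different plant states at harvest among those not tested.

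The other counts were set against splits of the counts as deposited, with 25 splits each. For infection in wild type the real counts and the highest other split were 4779 and 1 at 12 h, 6980 and 2 at 24 h, 991 and 2 at 48 h, 197 and 0 at 5 d, 2025 and 1 at 20 d, and 1969 and 361 at 30 d. For infection in 35S::AtCKX2 they were 5859 and 4541 at 12 h, 9533 and 4431 at 24 h, 4516 and 1808 at 48 h, 1790 and 795 at 5 d, and 2683 and 734 at 10 d. For the genotypes in mock plants they were 10394 and 371 at 12 h, 12536 and 3733 at 24 h, 7920 and 1 at 48 h, 11878 and 5639 at 5 d, 8773 and 1865 at 10 d, and 6041 and 500 at 30 d. No other split drawn called as many for any of these (1 of 25 as large). That is the smallest share that 25 splits can give, and not all splits were drawn, so by itself it does not exclude chance. Other splits did call as many for infection in wild type at 10 d (65 genes, 2 of 25 as large, highest other 891, a split that kept mock replicates 4 and 5 together). They also did for infection in 35S::AtCKX2 at 30 d (1179 genes, 3 of 25 as large, highest other 1458). For infection in 35S::AtCKX2, the highest other split at every time was the real one with 1 library of each group exchanged. The same held for the genotypes in mock plants, except at 30 d. Such splits keep most of the real grouping, so their counts do not show what chance alone gives.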

How the results depend on the processing

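The alternatives without 2 libraries of a group were chosen after the result was seen, and the others were planned. None of the log2 fold changes of AtCKX2 and the 4 identifiers reversed under any alternative run. The 25 counts were refitted 490 times with 1 library left out, and 413 stayed within 1.5 times. Of 160 other refits, 125 did. DESeq2's size factors within edgeR and the absence of a filter moved none of the 25 counts beyond 1.5 times, and no alternative moved the 6 counts for the genotypes in mock plants that far. The 4 identifiers passed at 24 h under all 26 alternatives. The cause was not tested for any count below.

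With only the groups compared, infection in wild type called 8100 genes at 12 h, 1897 at 48 h, 312 at 5 d and 10 at 10 d, and in 35S::AtCKX2 2405 at 12 h, 2209 at 48 h, 200 at 5 d and 4095 at 10 d. With DESeq2, infection in wild type called 1751 at 48 h, 396 at 5 d, 585 at 10 d and 3168 at 20 d, in 35S::AtCKX2 1783 at 30 d, and the interaction called 202 at 12 h, 1509 at 48 h, 1212 at 5 d, 1626 at 10 d and 1165 at 30 d. With all 130 libraries in 1 fit, infection in wild type called 2013 at 48 h, 388 at 5 d, 341 at 10 d and 3181 at 20 d, in 35S::AtCKX2 2888 at 5 d and 1121 at 10 d, and the interaction 57 at 12 h, 1494 at 48 h, 1322 at 5 d and 153 at 10 d. Without wild-type mock replicates 4 and 5, the interaction called 296 at 5 d and 1762 at 10 d, and infection in 35S::AtCKX2 5534 at 10 d. At 48 h, infection in wild type called 1679 without infected 35S::AtCKX2 replicates 4 and 5, and none of the 4 counts moved that far without infected wild-type replicates 2 and 5.

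The replicate numbers do not pair the libraries: in 0 of 19 comparisons did every same-numbered pair deviate together with r over 0.1, and in 0 did every library correlate best with its own number (r from -0.664 to 0.689). Infection in wild type at 5 d came nearest, with 4 of 5 libraries best with their own number and r from 0.082 to 0.332. With the replicate number as a block, infection in wild type called 38 genes at 10 d and 842 at 20 d, and the interaction 423 at 30 d. The other 22 counts stayed within 1.5 times.

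With 1 library left out, the lowest and highest counts were 360 and 1492 for infection in wild type at 48 h, 14 and 734 at 10 d, 1268 and 2794 at 20 d, and 1074 and 2376 at 30 d. For infection in 35S::AtCKX2 they were 796 and 4594 at 5 d and 538 and 1354 at 30 d. For the interaction they were 15 and 69 at 12 h, 2089 and 4809 at 24 h, 457 and 1680 at 48 h, 307 and 2399 at 5 d, 497 and 1936 at 10 d, and 348 and 1132 at 30 d. Alternatives for gene list medians were not run, as no list could be tested. Changes of 1.5-fold were mostly not recovered in simulated libraries with 200 genes changed. The parts of depth and of the spread between replicates in this were not separated.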

Other observations

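The tests of AtCKX2 against the genotype difference, of wild-type shoots in the samples, of shoot age and of the 48 h overlaps with libraries left out were chosen after the result was seen.

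In 35S::AtCKX2 the infection response at 48 h overlapped with that of 12 h (1227 genes fell at both against 418.0 for independent lists, and 760 rose against 281.3) and with that of 10 d. Its effects correlated across genes with r = 0.48 at 12 h, 0.18 at 24 h, 0.15 at 5 d, 0.42 at 10 d and -0.03 at 30 d. Among 17918 genes tested at 48 h and 10 d, 320 rose at both times against 149.3 for independent lists, 434 fell at both against 168.8, and 102 went opposite ways against 317.9. Infected 48 h replicates 4 and 5 lay nearest to infected 35S::AtCKX2 of 10 d and replicate 3 to that of 24 h. Without replicates 4 and 5, the overlaps with 10 d were 468 against 167.7, 464 against 204.0 and 112 against 371.4, and without replicate 3 they were 192 against 100.1, 370 against 134.1 and 87 against 233.7. Between 24 h and 10 d the directions were mostly opposite, with 1066 genes going opposite ways against 668.8, and 266 and 163 rising or falling at both against 343.3 and 325.4. The mock and infected libraries of different times are separate, so these overlaps share no control.

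Among 16740 genes tested at all 7 times, 350 rose and 650 fell at 3 or more times, 58 rose and 41 fell at 4 or more, and 1 rose at all 7. Both directions were called at different times for 695 genes. The 197 and 65 genes called at 5 d and 10 d limit how often a gene could recur, so these counts do not measure how common recurrence was.

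Of the 130 libraries, 22 lay nearer to the mean of another group than to that of their own group's other libraries, 11 of them to a group of another time and 1 to a group of the other genotype. That 1 was wild-type mock 10 d replicate 4, which lay nearest to mock 35S::AtCKX2 at 30 d. Infected wild type 48 h replicate 5 lay nearest to infected wild type of 24 h, and infected 35S::AtCKX2 48 h replicate 3 to infected 35S::AtCKX2 of 24 h. Solyc08g062340.3 stood at 199 and 259 CPM in these libraries. Wild-type mock replicates 1, 2 and 3 lay nearest to infected wild type of the same time at both 5 d and 10 d, and mock 35S::AtCKX2 12 h replicate 5 to infected 35S::AtCKX2 of 12 h. For these wild-type replicates, the mean of their own group's other libraries included mock replicates 4 and 5, which lay apart from them. Nearest to the mock group of their own genotype and time lay infected 35S::AtCKX2 5 d replicate 1 and 10 d replicate 1, and infected wild type 48 h replicate 2 and 30 d replicate 2. The others lay nearest to another time of their own genotype and treatment: wild-type mock 5 d replicate 5 to 48 h and 30 d replicate 2 to 20 d, infected wild type 20 d replicate 3 to 10 d, mock 35S::AtCKX2 24 h replicate 1 to 5 d, and infected 35S::AtCKX2 12 h replicate 3 and 5 d replicate 5 to 48 h, with 48 h replicates 4 and 5 given above.

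Within the infected 35S::AtCKX2 groups of 12 h to 5 d (20 libraries in 4 groups), libraries with less AtCKX2 had a smaller genotype difference. The measure was the mean log2 CPM of 767 genes at least 2-fold higher minus that of 886 genes at least 2-fold lower in mock 35S::AtCKX2 at all 4 times. The infected libraries entered the choice of these genes through the shared spread, scaling and filter, not through the fold changes between mock groups. Deviations from the group means correlated with Pearson's r of 0.868 (permutation within groups, p = 8e-05) and Spearman's rho of 0.752 (p = 0.0013, permutation). These 2 tests are of 1 relation, and their Benjamini-Hochberg adjusted permutation values are 0.00016 and 0.0013. Without the 2 libraries farthest from the median, r was 0.828. It was 0.771 to 0.972 within the groups of 5, 0.857 with library size removed, and 0.125 in the 20 mock libraries of the same times. Wild-type shoots in the samples are argued against as the only reason for the lower AtCKX2. For that, 9 libraries would need 50.5% to 83.2% of wild type. In these libraries the median over 20 to 24 genes at least 8-fold lower in mock 35S::AtCKX2 at 12 h to 5 d was at most 19.8% of the level in infected wild type. The library at 19.8%, infected 12 h replicate 3, would need 83.2%, and the upper quartile of its genes was 35.2%. A smaller share of wild type was not tested and stays open: the medians were 0 to 19.8% in the 9 libraries and 0 to 9.24% in the others. These genes need not be at 0 in 35S::AtCKX2 itself, so the medians do not measure a share of wild type. The genotype difference may go with the amount of transgene transcript in infected shoots. That both follow a shared state of the shoot, such as the stage of infection in each sample, stays open.

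The genotype difference in mock plants at 10 d ran against the change of wild-type mock plants from 12 h to 30 d, with r = -0.516 across 15915 genes and no shared library, whereas r was 0.26 at 24 h, 0.12 at 48 h and 0.16 at 5 d. An earlier developmental state of 35S::AtCKX2 shoots at 10 d could give this sign. The relation rests in part on wild-type mock replicates 4 and 5: r was -0.234 with them left out and -0.705 with only them, so the data do not settle it.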
